A study of Apostichopus japonicus with 9 samples.

How the data were processed

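Poly(A) RNA from the intestine of the sea cucumber Apostichopus japonicus, a farmed echinoderm that does not regulate the salt content of its body fluid tightly, was sequenced in 9 libraries. Per the labels' protocols, RNA of 3 animals was pooled in equal amounts for each library, poly(A) RNA was fragmented, copied with random primers, amplified, circularised and sequenced on a BGISEQ instrument. Per the series' design text, animals had been held at 15 °C and then assigned to control sea water (labelled 30), diluted sea water (labelled 20) or concentrated sea water (labelled 40), with 20 animals per group and salinity changed by 2.5 every 6 h. These salinities are written with a percent sign in some places and without a unit in others, so only the labelled numbers are used here. The time spent at the final salinity is not given in the sources used here. The labels do not say whether the pools of a group came from different animals or tanks, so p-values measure the spread between pooled libraries, which may be partly technical.

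The deposited files hold, for each library, estimated counts per gene model (not normalized and often not whole, per the file headers and values), FPKM and the gene model length. The authors' FPKM values are scaled for gene model length and for the reads assigned in the library, as inferred from the values. Recomputing them from the deposited counts and lengths gave the same value within 5% for 91.9% of genes with 10 or more counts. CASAVA 1.5 is named in the submitters' processing notes. The read aligner, counting program, genome build and annotation are not given in the sources used here. A gene with no assigned read has no line in a library's file and was set to 0. The estimated counts were deposited with up to 2 decimals, and a value is called whole where these decimals are absent or 0, with no further tolerance. In each library about 50% of the non-zero estimated counts were whole numbers (48.9% to 54.4%). A value that is not whole can arise where reads are divided between similar gene models, but the counting program is not known here. Genes with such values are therefore uncertain where near-identical copies exist, and whole values do not exclude shared reads. Of the 14191 genes tested, 6153 had whole values in every library. Lengths were multiples of 3 for 93.5% of gene models, so they are mainly coding lengths, with a median of 951 bases. In 7 models the listed length exceeded 20000 bases, up to 1761004 bases, and these models took 1.62% to 3.25% of counts.

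The files do not pair the AJAP identifiers with gene names. None of the 27269 identifiers (0 matches) occurs in the RefSeq gene table of the species (assembly ASM3797524v1), and no coordinates are given. The 30 lists of osmoregulation, stress, digestive, metabolic and cell type genes that were fixed in advance could therefore not be matched, and no list test was run. The rule for named genes was then limited to at most 2 identifiers per direction and comparison. These are the genes with the smallest unadjusted p where fewer than 4 genes passed, given as values. Other identifiers named in the text were chosen after their values were seen.

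Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood test was run with robust dispersion estimates in a single fit of all 9 libraries with the salinity group as the only term. The 3 pairwise comparisons and a joint test of any difference among the 3 groups were made, with Benjamini-Hochberg adjustment and a threshold of 0.05. A standard error (SE) of a log2 fold change is the fold change divided by the square root of the test's F. Expression values are CPM, that is counts relative to the TMM-scaled library size. The fitted biological coefficient of variation was 69.4%. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at 1 FPKM or more in at least 3 libraries, fits of 2 groups only, the replicate number as a block, a 2-fold minimum, and the omission of each library. These and the main tests were chosen before the data were examined. Library weights (limma voom), the removal of a co-varying gene set together with the 7 longest models, and the omission of libraries under DESeq2 were added after seeing the data. Overlap of the responses was set beside 100 simulated draws. In each draw all 9 libraries, controls included, were drawn anew with no group difference and with genes independent of each other. Both unchanged groups were compared with the same 3 simulated controls.

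The tests were checked on simulated data in which 200 of 14191 genes were changed, with the real means, library sizes and fitted dispersions, in 3 draws per comparison. The dispersions were those fitted by edgeR, which may favour edgeR. The share of false calls also depends on how many genes were changed, so it need not hold for the real calls. For SD20 against SD30, edgeR recovered 2.49% of 4-fold, 42.3% of 16-fold and 70.2% of 64-fold changes, and 2.97% of its calls were false. DESeq2 recovered 22.4%, 77.1% and 88.9% of them, and 30.1% of its calls were false. For SD40 against SD30, edgeR recovered 2.49%, 50.2% and 73.7%, with 6.32% of calls false, and DESeq2 had 32.3% of calls false. For SD40 against SD20, edgeR recovered 1.99%, 38.3% and 68.7%, with 3.98% of calls false, and DESeq2 had 28.8% of calls false.

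Total estimated counts ranged from 2834168 to 4060892 per library. To compare detection, each library was thinned at random to 2800000 reads, or to 900000 reads after the 100 most abundant genes had been left out, and results were averaged over 10 thinnings. Shares of counts in single libraries have 95% Wilson intervals no wider than 0.106 percentage points. Intervals and floors cover counting error only, since reads carried no molecular identifiers. A gene with no read in a group was given a floor of 3 counts over the group. Library-level measures were compared with exact two-sided permutation tests in Python 3.11.15 with scipy 1.17.1. With 3 libraries against 3 the smallest possible p is 0.1. All pairs of libraries of a group differed by more than counting noise, with a chi-square of their counts of 31.5 to 186 per degree of freedom. No pair was thus a single library deposited again, and the 9 libraries were counted as the labels give them. Repeat preparations of a single pool would also exceed counting noise, so this does not show that the pools held different animals.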

Results

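The intestinal transcriptome was measured by RNA sequencing in 9 pooled libraries, 3 from sea cucumbers in control sea water (SD30), 3 from animals in diluted sea water (SD20) and 3 from animals in concentrated sea water (SD40). The design asks how gene expression in the gut differs at low and at high salinity from the control. Estimated counts summed to 3442227, 3636091 and 3728855 in the SD20 libraries, to 3373860, 4060892 and 3340018 in the SD30 libraries, and to 4034952, 3487323 and 2834168 in the SD40 libraries. Across all libraries 27269 gene models had at least some assigned reads, 12361 of them in every library, and 14191 were abundant enough to be tested. Genes are given by the identifiers of the gene models (AJAP numbers), because no gene names are paired with them in the sources used here.

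A small number of transcripts dominated the intestinal RNA in every group. On average over the libraries the most abundant were AJAP12149, with a coding length of 1587 bases, and AJAP07929, with a length of 4554 bases. AJAP12149 took 6.90% ± 0.522 of counts in SD20, 14.1% ± 8.84 in SD30 and 8.50% ± 4.41 in SD40 (SD, n = 3 each). AJAP07929 took 8.97% ± 1.14, 11.3% ± 6.66 and 8.87% ± 5.30. Another abundant transcript, AJAP26202, took 4.62% ± 1.32, 6.88% ± 1.10 and 5.12% ± 0.559. In SD30 replicate 2, AJAP12149 and AJAP07929 reached 24.3% and 18.7% of all counts. The order differed between libraries. In SD40 replicate 3, AJAP26202 (5.73%) exceeded AJAP12149 (3.70%) and AJAP07929 (2.79%), and in SD30 replicate 1, AJAP13414 led with 10.2%. These genes were chosen for their abundance after the values were seen.

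The 10 most abundant genes of each library together took 30.4% ± 0.887 of counts in SD20, 48.0% ± 13.1 in SD30 and 34.2% ± 9.36 in SD40 (SD, n = 3 each). The 3 SD20 libraries all lay below the 3 SD30 libraries, where the share was 44.6%, 62.5% and 37.0%. The exact permutation p was 0.1, the smallest that 3 libraries against 3 can give, and 0.3 after adjustment over 18 library-level comparisons. SD40 overlapped both other groups (exact p = 0.2 against SD30 and 0.6 against SD20). The TMM scaling factor was 1.34 to 1.42 in SD20, 0.492 to 1.18 in SD30 and 0.996 to 1.12 in SD40.

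More genes were detected at low salinity than in the control. At 2800000 reads per library, 21154 ± 949 genes had at least 1 read in SD20, 17772 ± 1672 in SD30 and 19623 ± 1500 in SD40 (SD, n = 3 each). The SD20 and SD30 libraries did not overlap, with the smallest possible exact permutation p of 0.1 and 0.3 after adjustment over the 18 comparisons. SD40 replicate 1, with 21342 genes, lay among the SD20 libraries, while SD40 replicates 2 and 3, with 18582 and 18944, lay within the range of the SD30 libraries (16748 to 19702). With the 100 most abundant genes left out and 900000 of the remaining reads drawn, the means were 20122 ± 979, 17593 ± 1174 and 18643 ± 1708 (SD, n = 3 each).

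**Figure D1:**
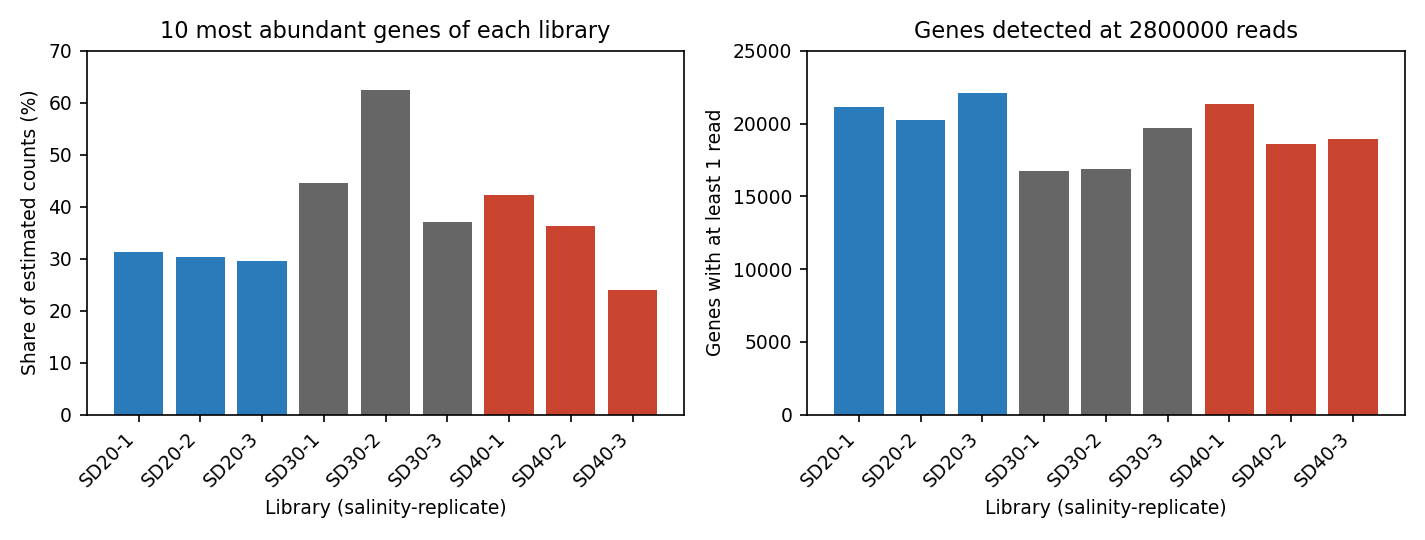
Left, the share of estimated counts (%) taken by the 10 most abundant genes of each library, and right, the number of genes with at least 1 read after thinning to 2800000 reads, 1 bar per library and colours for the salinity groups (SD20 blue, SD30 grey, SD40 red). The 3 SD30 bars on the left (37.0% to 62.5%) are all above the SD20 bars, and on the right all below them.

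Libraries of a group resembled each other only slightly more than libraries of different groups. Over the 14191 tested genes, the mean Pearson correlation of log2(CPM + 1) was 0.774 within groups and 0.749 between groups. Of the 280 ways to divide the 9 libraries into 3 groups of 3, 26 gave a within-group correlation as high (exact one-sided permutation p = 0.0929). For SD20 and SD30 the values were 0.791 within and 0.731 between, the highest of the 10 splits of those 6 libraries. For SD40 and SD30 they were 0.757 within and 0.763 between, and 8 of 10 splits gave a value as high. For SD40 and SD20 they were 0.772 and 0.753, the second highest of 10 splits. These are correlations across genes, which are not independent replicates.

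Low salinity was compared with the control first. No gene passed the adjusted threshold in edgeR's quasi-likelihood test for SD20 against SD30 (0 of 14191, lowest adjusted p = 0.370). An unadjusted p under 0.05 was found for 1738 genes, where 710 would be expected with no effect. The 710 applies to each comparison and is only an average. Other splits of these 6 libraries gave 311 to 1088 such genes. Of these 1738 genes, 791 were higher and 947 lower in SD20, and with libraries scaled to their totals instead of TMM the split was 2462 higher and 173 lower. The 1738 became 939 without SD20 replicate 3 and 1068 without SD30 replicate 1. DESeq2 called 348 genes, 86 higher and 262 lower. On data simulated for this comparison with edgeR's fitted dispersions, 30.1% of its calls were false, against 2.97% for edgeR. That share need not hold for the real calls. The DESeq2 count was 86 without SD20 replicate 3, 100 without SD30 replicate 1, 190 without SD20 replicate 1 and 701 without SD30 replicate 3. All 3 SD20 libraries lay above or all below the 3 SD30 libraries for 22.1% of tested genes (1847 higher, 1285 lower). Without ties, the average of this share over all splits of 6 libraries is 10%. The other splits were not counted and genes are not independent replicates, so this does not measure an excess over chance.

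The genes with the smallest p that were higher in SD20 were AJAP14621 and AJAP09474. AJAP14621 stood at 31.5 ± 14.3 CPM in SD20, 1.36 ± 1.47 in SD30 and 6.37 ± 0.620 in SD40 (SD, n = 3 each), a log2 fold change of 4.35 against the control (SE 0.73, edgeR adjusted p = 0.370). AJAP09474, a long gene model of 7212 bases, stood at 442 ± 307 CPM in SD20, 12.9 ± 8.43 in SD30 and 108 ± 40.5 in SD40. Its log2 fold change against the control was 5.09 (SE 0.92, edgeR adjusted p = 0.370). Both were also higher in all 3 SD40 libraries than in any SD30 library. They were chosen for small p against these same SD30 libraries, which favours low SD30 values, so this is not separate support. The genes with the smallest p that were lower in SD20 were AJAP28182 and AJAP23480. The short gene model AJAP28182, of 237 bases, stood at 110 ± 17.01 CPM in SD20, 1111 ± 906 in SD30 and 278 ± 51.5 in SD40. Its log2 fold change was -3.33 (SE 0.61, edgeR adjusted p = 0.370). AJAP23480 stood at 3.95 ± 1.08 CPM in SD20, 19.2 ± 1.38 in SD30 and 7.23 ± 0.993 in SD40, with a log2 fold change of -2.27 (SE 0.43, edgeR adjusted p = 0.370). The log2 fold change of AJAP14621 was 5.77 without SD30 replicate 3, and that of AJAP28182 was -2.51 without SD30 replicate 1. Leaving out each library gave 4.57 to 5.51 for AJAP09474 and -2.54 to -2.08 for AJAP23480. None of the 4 passed with edgeR, each passed with DESeq2, and all 4 had values that were not whole, so they are uncertain where similar gene models exist.

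High salinity differed less from the control in the number of low p-values. For SD40 against SD30, 0 of 14191 genes passed in edgeR's test (lowest adjusted p = 0.235), and 894 had an unadjusted p under 0.05, 492 higher and 402 lower in SD40. With library totals as the scaling the split was 1096 higher and 145 lower. DESeq2 called 44 genes, 15 higher and 29 lower, and on simulated data for this comparison 32.3% of its calls were false. Another split of these 6 libraries gave 251 DESeq2 calls. All libraries of one group lay above those of the other for 9.46% of tested genes, close to the average of 10% over all splits.

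The gene with the smallest p was AJAP01274, with a coding length of 987 bases. It stood at 67.0 ± 15.3 CPM in SD40 and 8.94 ± 0.553 in SD30 (SD, n = 3 each), a log2 fold change of 2.90 (SE 0.39, edgeR adjusted p = 0.235). The next gene higher in SD40, AJAP20386, stood at 16.0 ± 4.87 CPM against 3.06 ± 0.969, a log2 fold change of 2.38 (SE 0.51, edgeR adjusted p = 0.770). AJAP25896, of 1272 bases, had no read in any of the 3 SD40 libraries, which allows up to 0.276 CPM over the group, and 67.3, 24.9 and 110 estimated counts in the SD30 libraries. Its pooled SD30 level was 93.5-fold above that floor (edgeR adjusted p = 0.235). This covers counting error only and leaves out the spread between the SD30 libraries, at 34.9, 12.6 and 28.0 CPM. Without the filter on low counts this gene passed (edgeR adjusted p = 0.0411, and 2.4e-07 with DESeq2 to 0.987 over its 20 alternatives). AJAP29425 had 3, 2 and 0 counts in SD40 and 22, 16 and 77 in SD30, a log2 fold change of -4.79 (SE 0.80, edgeR adjusted p = 0.763). The values of AJAP20386 and AJAP25896 were not whole, and those of AJAP01274 and AJAP29425 were whole in every library.

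The direct comparison of high with low salinity gave a single gene. AJAP01274 was higher in SD40 than in SD20, at 67.0 ± 15.3 against 3.88 ± 0.717 CPM (SD, n = 3 each), a log2 fold change of 4.10 (SE 0.41, edgeR adjusted p = 0.0340), and it was the single gene past the threshold in the joint test of the 3 groups (edgeR adjusted p = 0.0380). Its counts were 14, 21 and 22 in SD20, 16, 18 and 37 in SD30 and 339, 260 and 146 in SD40, and in the authors' FPKM it stood at 5.32 ± 1.04, 6.86 ± 3.79 and 71.0 ± 17.4. The call ended when any 1 of the 9 libraries was left out (edgeR adjusted p from 0.0720 to 0.540), while the log2 fold change stayed between 3.96 and 4.28. It also ended with scaling to library totals, with limma on FPKM, in a fit of the 2 groups only and with the replicate number as a block (adjusted p from 0.107 to 0.641).

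In SD40 against SD20, 914 genes had an unadjusted p under 0.05, 572 higher and 342 lower in SD40. With library totals as the scaling the split was 256 higher and 458 lower. DESeq2 called 77 genes, 50 higher and 27 lower. Without SD40 replicate 1 the number at an unadjusted p under 0.05 was 2061. The libraries of the groups did not overlap for 13.4% of tested genes, where the average over all splits is 10% and the other splits were not counted. The next gene higher in SD40 was AJAP30105, with 190, 83 and 342 counts in SD40, 25, 4 and 84 in SD30 and 1, 3 and 1 in SD20, a log2 fold change of 7.33 (SE 1.11, edgeR adjusted p = 0.365). It was 8.00 without SD20 replicate 2 and 6.47 without SD40 replicate 3. The genes with the smallest p that were lower in SD40 were AJAP25896 and AJAP16506. AJAP25896 stood at 12.2 ± 5.91 CPM in SD20 (SD, n = 3). Its pooled SD20 level was 44.1-fold above the SD40 floor, by counting error only (edgeR adjusted p = 0.365). AJAP16506 stood at 14.2 ± 3.74 CPM in SD20, 8.81 ± 2.84 in SD30 and 1.70 ± 0.546 in SD40, a log2 fold change of -3.03 between SD40 and SD20 (SE 0.52, edgeR adjusted p = 0.524).

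**Figure D2:**
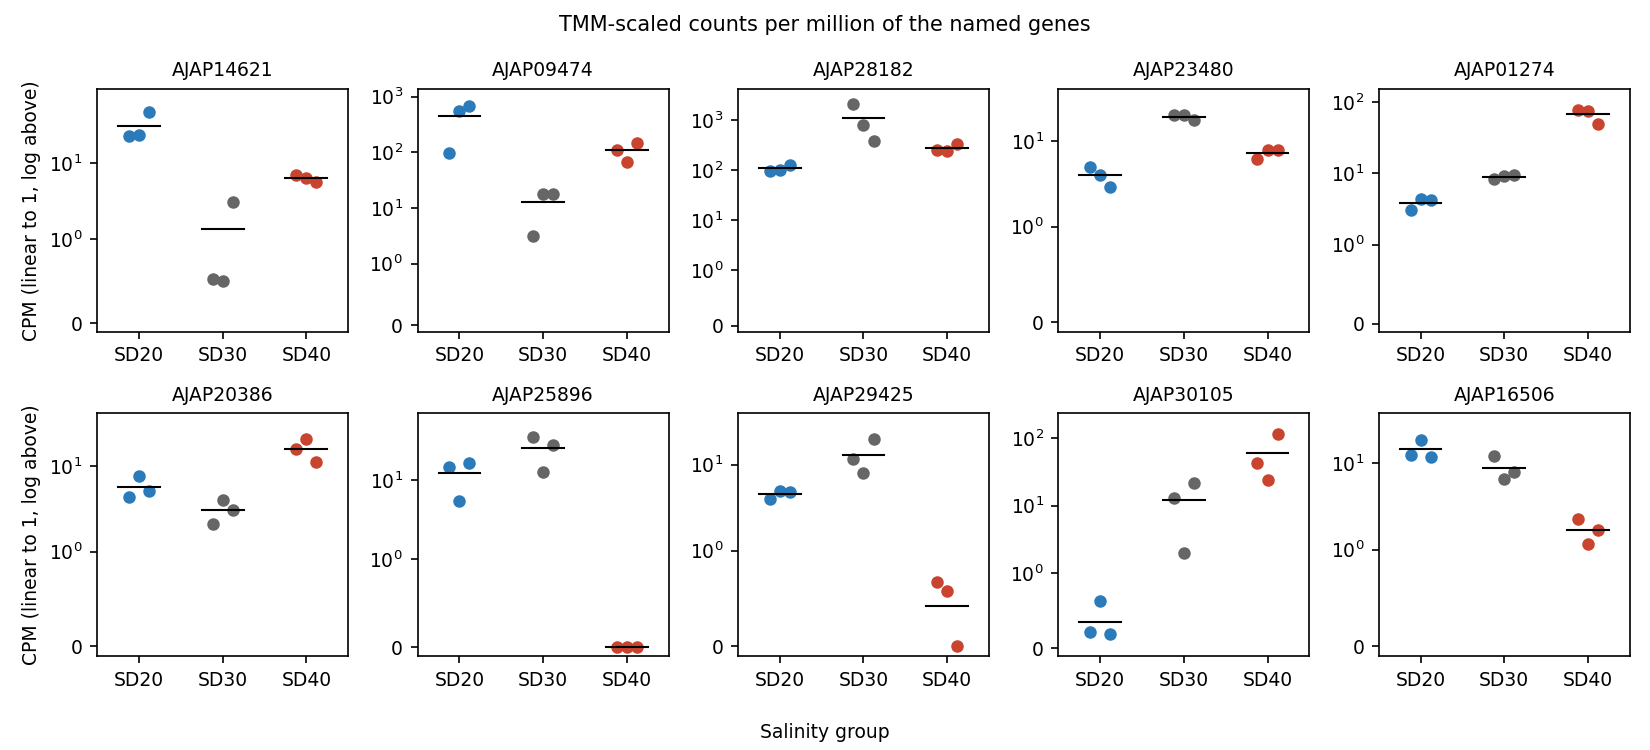
Expression (TMM-scaled CPM) of the 10 named genes on an axis that is linear up to 1 and logarithmic above, with 1 point per library (n = 3 per salinity group) and a line at the group mean. AJAP01274 is at 67.0 CPM on average in SD40 against 8.94 in SD30 and 3.88 in SD20, and AJAP25896 has no read in SD40.

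The responses to low and to high salinity were then set side by side. No gene was called by edgeR in both comparisons against the control (0 genes), and DESeq2 called 9 in both with the same direction, where independent lists would share 0.626. That value leaves out the shared controls, which were not simulated for DESeq2. At an unadjusted p under 0.05 in edgeR, 219 genes were higher and 166 lower in both SD20 and SD40 than in SD30, and 3 went in opposite directions. The balance depended on the scaling, with 685 higher and 20 lower when libraries were scaled to their totals and 701 and 30 with limma on log2(FPKM + 1). Independent lists would share 27.4 and 26.8 genes. Unchanged groups compared with the same 3 controls, all of them simulated, shared 117 and 42.0 on average over 100 draws. The simulated lists held 632 genes each on average, fewer than the 1738 and 894 of the real ones, and longer lists share more genes, so these numbers are not directly comparable. The 219 became 117 without SD20 replicate 3, 132 without SD30 replicate 1, 400 without SD30 replicate 3, and lay between 219 and 400 without SD40 replicate 2. The 166 became 103 without either of the first 2 of these libraries, 250 without SD30 replicate 2 and 351 without SD30 replicate 3. The 3 in opposite directions became 20 without SD40 replicate 1. The fold changes of the 2 comparisons correlated across genes at r = 0.665, against 0.521 in the simulation, and their covariance was 1.18 against 0.521, a difference of 0.663. Without SD40 replicate 1 the correlation was 0.381, and without SD30 replicate 3 it was 0.807. The covariance was 3.04 without SD30 replicate 3 and 1.99 without SD30 replicate 2. These 2 fits tested more genes (15752 and 15833) and had 2 controls. No simulation was made for fits without a library, so their values are not comparable with the simulated ones. The 3 control libraries cannot be divided into 2 sets of at least 2, so part of the excess may come from the shared controls. Genes were simulated independently, without the joint variation of genes in the real controls, so the simulation may also understate what shared controls give.

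Some genes differed strongly between libraries of the same group. A set of 18 genes, counting AJAP13414 itself, went up and down together across libraries. It was found after the data were seen, by correlation above 0.95 with the abundant transcript AJAP13414 and a log2 range of at least 5. The set took 27.8% of all counts in SD30 replicate 1 but 0.0673% and 0.498% in SD30 replicates 2 and 3. In the SD20 libraries it took 0.0591%, 4.24% and 3.08%, and in the SD40 libraries 0.283%, 0.00272% and 0.243%. Its mean log2(CPM + 1) was 7.59 ± 3.32 in SD20, 8.71 ± 4.36 in SD30 and 4.51 ± 3.05 in SD40 (SD, n = 3 each), with no group difference past the threshold (exact permutation p = 0.429 over 280 splits). AJAP13414 alone took 10.2% of counts in SD30 replicate 1 and 0.000192% in SD40 replicate 2.

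Libraries also differed in how strongly long gene models were represented. Spearman's rho between gene model length and a gene's deviation from its mean over libraries was 0.146, -0.0234 and 0.201 in SD20, -0.0876, -0.0975 and -0.0281 in SD30, and 0.207, -0.181 and -0.145 in SD40. Across the 9 libraries this length trend went with the number of genes detected at 900000 reads (Pearson's r = 0.915, exact permutation p = 0.00173, and Spearman's rho = 0.833, exact permutation p = 0.00827). This was the single relation across libraries that was computed. Without the 2 libraries farthest from the median, SD40 replicate 1 and SD20 replicate 3, r was 0.811 (exact permutation p = 0.0357) and rho was 0.679 (exact permutation p = 0.110). Deviations from the group means of the 9 libraries correlated at r = 0.906, and no sequencing batch is given in the labels.

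**Figure D3:**
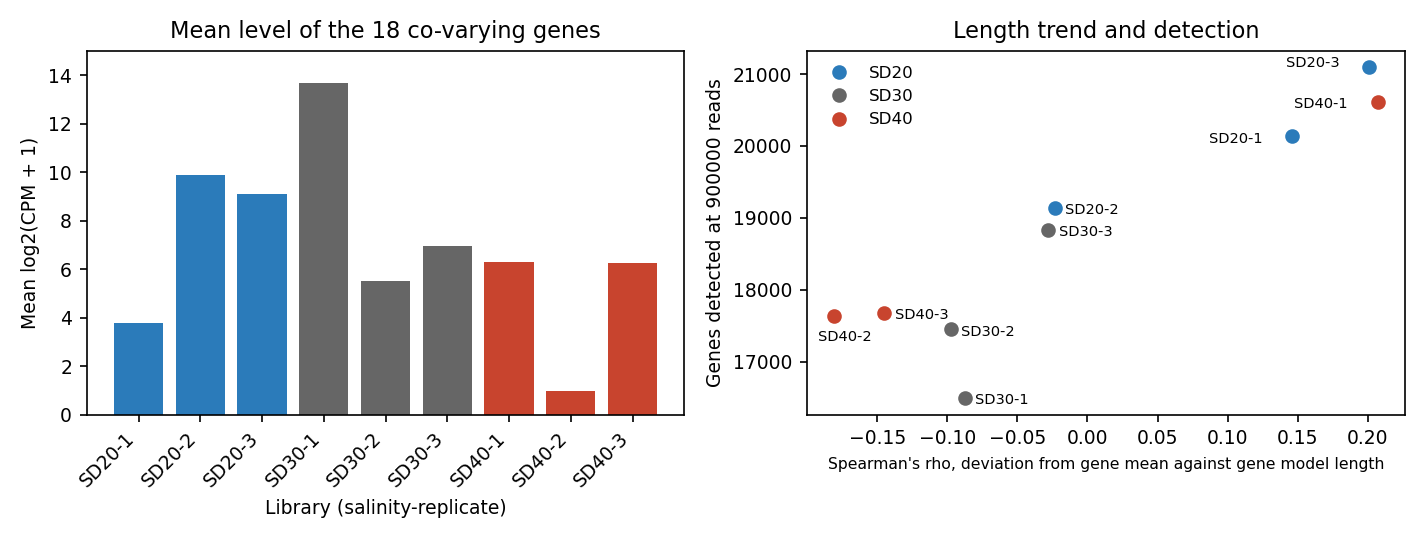
Left, the mean log2(CPM + 1) of the 18 co-varying genes in each library (bars), and right, the number of genes detected at 900000 reads against Spearman's rho of expression deviation with gene model length (1 point per library, coloured by salinity group). SD30 replicate 1 has the highest bar and SD40 replicate 2 the lowest, and SD40 replicate 1 lies beside SD20 replicates 1 and 3 on the right.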

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

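AJAP01274 stood out because its responses to low and to high salinity differed by the direct test of SD40 against SD20 (edgeR quasi-likelihood test, adjusted p = 0.0340). It was higher in each of the 3 SD40 libraries (339, 260 and 146 counts) than in any of the 6 others (14 to 37 counts). All its counts were whole numbers. The call was lost when any 1 of the 9 libraries was left out (edgeR adjusted p from 0.0720 to 0.540). Against SD30 it did not pass in SD40 (edgeR adjusted p = 0.235), and no gene passed in SD20.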

How the results depend on the processing

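Library weights, the removal of the co-varying set and the omission of libraries under DESeq2 were chosen after the results were seen. For SD20 against SD30 no gene passed under 20 of 21 alternatives, the exception being DESeq2 with 348 calls. For SD40 against SD30, 1 gene passed with no filter on low counts and 44 with DESeq2. For SD40 against SD20, DESeq2 called 77 genes, and 0 passed without scaling beyond library totals, with limma on either FPKM pseudocount, in a fit of the 2 groups only, or with the replicate number as a block. The joint test gave 188 calls with the DESeq2 likelihood-ratio test and 0 without scaling, with limma on FPKM and with the replicate block. The genes called in both comparisons against the control numbered 9 with DESeq2 and 0 under the other alternatives. Leaving out each library in turn gave 0 to 0 calls in edgeR for every comparison and 0 to 0 shared calls. The cause of these differences was not tested, except that DESeq2 made more false calls on the simulated data, which were drawn with edgeR's fitted dispersions. Over 20 alternatives per gene, no named gene changed direction, but fold sizes moved. For SD20 against SD30, scaling to library totals and limma on log2(FPKM + 1) gave log2 fold changes of -1.37 and -1.25 for AJAP23480 and of -2.19 and -2.04 for AJAP28182, while scaling to totals gave 5.86 for AJAP09474 and 4.96 for AJAP14621. For SD40 against SD30, limma on log2(FPKM + 1) gave 1.54 for AJAP20386 and -2.47 for AJAP29425, and for SD40 against SD20 it gave 4.73 for AJAP30105. AJAP25896, with no read in SD40, moved from -9.54 in the main fit to -3.78 for SD40 against SD30. For SD40 against SD20 it moved from -8.50 to -3.65. AJAP01274 in SD40 against SD20 kept its call under 6 of 20 and had log2 fold changes of 3.49 to 4.28 (adjusted p at most 0.641). Scaling to library totals moved the median log2 fold change of all genes from 0.07 to 0.92 in SD20 against SD30, from 0.11 to 0.60 in SD40 against SD30 and from 0.04 to -0.33 in SD40 against SD20. Equal replicate numbers showed no clear pairing of the libraries. The correlation of their deviations from group means was 0.0368 on average over 9 pairs (-0.113 to 0.203) and exceeded 0.1 in 2. Pairs of unequal number gave -0.0185 on average (-0.280 to 0.248). With 3 libraries per group a partial pairing is not excluded. Under the block the genes at unadjusted p under 0.05 numbered 1588, 698 and 765 in the 3 comparisons and 1027 in the joint test. The gene list tests planned in advance and their alternatives were not run, because the identifiers could not be matched to names. Without any 1 library, genes at unadjusted p under 0.05 numbered 939 (without SD20 replicate 3) and 1068 (without SD30 replicate 1) to 2383 for SD20 against SD30, 616 to 1253 for SD40 against SD30, and 611 to 2061 (without SD40 replicate 1) for SD40 against SD20. On simulated data with 200 changed genes edgeR found few of the 4-fold changes (2.49% for SD20 against SD30), and smaller changes were not simulated.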

Other observations

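Some transcripts were present in one group and missing from another. Of genes with 10 or more counts in all 3 libraries of one group and no read in the 3 of the other, 8 were seen in SD20 and not in SD30, with 0 in the other direction. In SD40 against SD30 there were 2 and 3, and in SD40 against SD20 there were 0 and 6, the 6 being present in SD20. AJAP25896 and AJAP22456 were the 2 genes with 10 or more counts in each of the 6 SD20 and SD30 libraries and no read in SD40. AJAP22456 had 10, 45 and 230 counts in SD20 and 14, 45 and 49 in SD30, all whole.

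The tests in this part other than the splits for edgeR calls, the splits for present and absent genes and the test by gene length were chosen after the results were seen. As many present and absent genes as in SD40 against SD20 were found in 3 of the 10 splits of those libraries, with up to 17 in another split (6 in the real one). For SD20 against SD30 the real number was 8 and the highest other 10, and for SD40 against SD30 they were 5 and 7, and 10 splits are too few for a share under 0.05. As many genes as in SD40 (2) were absent from 2 of the 84 triples of libraries, so another triple reached the same number. This count was made because the genes had been seen, and 3 groups were looked at, so it does not exclude chance.

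For edgeR calls, 10 splits per comparison are too few for a share under 0.05. SD20 against SD30 and SD40 against SD30 had 0 calls in the real and in all other splits (10 of 10 as many each), and SD40 against SD20 had 1 call in the real split and at most 0 in the others (1 of 10). At an unadjusted p under 0.05 the real count and the highest of the other splits were 1738 and 1088 for SD20 against SD30 (1 of 10 as many), 894 and 1699 for SD40 against SD30 (6 of 10), and 914 and 1946 for SD40 against SD20 (2 of 10). The split with 1946 genes set SD20 replicates 1 and 3 and SD40 replicate 1 against SD20 replicate 2 and SD40 replicates 2 and 3, and DESeq2 called 635 genes in it against 77 in the real one (2 of 10 as many). For SD40 against SD30 DESeq2 called 44 genes in the real split and up to 251 in another (7 of 10 as many). The split with 251 set SD30 replicates 1 and 2 and SD40 replicate 2 against SD30 replicate 3 and SD40 replicates 1 and 3. Splits with several times the real number may follow a structure of the samples other than salinity, for which no separate test was made. In the split with 1946 genes, the first 3 libraries are those with the most genes detected and the strongest representation of long gene models. For the joint test, 1 of 100 splits of the 9 libraries had as many calls (1 in the real split, at most 0 in the others), a share under 0.05. This count sets 1 call against 0 and rests on 1 gene. The call is lost (0 calls) when any 1 of the 9 libraries is left out or with the replicate number as a block. The count therefore does not exclude chance. As many genes at an unadjusted p under 0.05 were found in 10 of 100 splits (1228 in the real split, 1852 in the highest other), so chance cannot be excluded for these either. Without SD20 replicate 3 the 1228 became 746, and without SD40 replicate 1 it became 2099.

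The higher number of detected genes in SD20 than in SD30 was larger than the pooled SD of the libraries after technical corrections. At equal reads the gap was 3381 genes (pooled SD 1359), which argues against sequencing depth as the whole cause, and without the 100 most abundant genes it was 2529 (pooled SD 1081), which argues against the dominant transcripts as the whole cause. Among the shortest of 4 equal classes of gene models it was 552 (pooled SD 244) and among the longest 759 (pooled SD 320). This argues against a gap confined to long gene models, but not against a library property that moves detection at every length. The length trend also separated the SD20 from the SD30 libraries (mean rho 0.108 and -0.0710, exact permutation p = 0.1). A property of the RNA or library that moves detection and the length trend together may still contribute, since both varied within SD40, and a salinity effect stays open and untested beyond the exact p of 0.1.

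The mean level of the 18 co-varying genes ranged more widely within each group than the group means differed. The exact permutation test of the groups over 280 splits gave p = 0.429. The range within SD30 (8.16 on the log2 scale) exceeded the largest difference of group means (4.20). A range of single libraries and a difference of means are unlike measures. By SD, SD30 (4.36) lay slightly above 4.20, and SD20 (3.32) and SD40 (3.05) lay below it. Libraries of the same labelled salinity thus differed, which argues against salinity as the whole cause of the set's spread. The set was built, after the values were seen, around the leading transcript of SD30 replicate 1. A wide range within SD30 was thus favoured by the choice, and these values do not test whether salinity contributes. Whichever library was left out, the other 8 spanned at least 8.90 log2 units, and without both the highest and the lowest the span was 6.10, which argues against a single aberrant library. A candidate explanation is that the pools differed in gut region, feeding state or cell content, which cannot be examined without gene names. For comparison, 100 random draws were made from all genes with as wide a range, the set included and repeats possible. Counting the drawn gene itself, the median number of genes correlated above 0.95 was 1 and the highest was 23. The median draw thus had no partner.

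The 348 DESeq2 calls in SD20 against SD30 were more than in any other split of the 6 libraries (highest 124, 1 of 10 as many), and 10 splits are too few to exclude chance. Of these genes 347 had an unadjusted p under 0.05 in edgeR and 348 the same direction, with edgeR adjusted p from 0.370 to 0.409. Both tools used the same counts and groups, so this agreement is not independent support for the calls. Without SD30 replicate 1 DESeq2 called 100 genes, against 267 and 701 without the other control libraries, but also 86 without SD20 replicate 3 and 190 without SD20 replicate 1. Whether that control library makes most of the calls stays open. The calls may hold real low-salinity effects as well as false ones, as the 30.1% of false calls in simulated data leaves open.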
